A study of Escherichia coli with 40 samples.

How the data were processed

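The series holds RNA-seq libraries of Escherichia coli K-12 MG1655 sampled before and after rifampicin. Per the labels' protocols, ERCC spike-in RNA was added to equal amounts of total RNA before rRNA was depleted, and strand-specific paired-end libraries were made. Per the submitters' processing notes, STAR 2.7.11b and RSEM 1.3.3 were used with build ASM584v2. Each of 8 deposited tables holds 1 strain and replicate number at 0, 2, 4, 8 and 16 min, and is taken here to be 1 culture. Groups were taken from the labels: 2 strains at 5 times, with 4 cultures each. The titles number the cultures as replicates (rep2, rep3, rep4 and rep6), and that number is called batch here. The labels do not say more about how the replicates were made. Each table also has 1 min columns, 16 in all, that belong to no sample in the labels and were not used.

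The 0 min column of each deposited table holds counts: whole numbers, with every 0 written as 1. The later deposited columns hold a signal that, read from the values, is the gene count times one factor per library. That factor brings the spike-ins near, but not equal to, the 0 min library of the same table. Values under 1 are written as 1. Over libraries 1 read was worth 0.204 to 1.00 units, so a value of 1 can stand for up to 4 reads. All values under 1000 reads were whole multiples of that step (tolerance 0.01 read), and this step was used only to estimate totals. Spike-in totals after 0 min lay between 85.5% and 131% of that at 0 min. The highest was the 8 min library of the culture labelled fbp of batch 3, with 238875 against 181807 at 0 min. The deposited half-life column is a score in minutes that, read from the values, the authors computed from the slope of log10 percent remaining over all times in the table, 1 min among them; its medians are given beside the rates fitted here and were not tested. The factor per library rests on the spike-ins, so rates depend on how exactly these were added; an error there shifts all genes of a library alike.

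All 4639 gene identifiers matched the reference of the same build, 4288 protein coding, 86 tRNA, 97 other non-coding, 145 pseudogene and 22 rRNA, besides 92 spike-ins. rRNA, 0.172% to 1.86% of gene values, was left out, which leaves 4617 genes. The 10 most abundant genes held 24.5% of the 0 min libraries. Repeated tRNA genes share reads and their values are uncertain, and cysC and cysN overlap by 1 base. At 0 min a level of 10 RPM stood for 50 or more reads per library; intervals were not computed for single genes, since the spread between cultures entered each test.

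Each culture's table was multiplied by one number so that its 0 min sum over genes was 1e+06, which keeps ratios between times. The decay rate of a gene in a culture is minus the least squares slope of log2(value + 1) against minutes over 0, 2, 4 and 8 min, and a half-life is 1 over the rate. Genes with a mean of at least 10 at 0 min, 2962, were tested. Rates were compared with limma 3.58.1 (lmFit, and eBayes with a trend on level) in R 4.3.3, with 1 value per gene and culture, and each strain's rate was tested against 0 in the same fit. Levels at 0 min were compared with edgeR 4.0.16 (TMM factors, quasi-likelihood test), the choice set for count files, and with DESeq2 1.42.0 as another tool. The SE of a level by edgeR is an approximation, the size of the log2 difference divided by the square root of the test's F statistic. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Single values per culture were compared by exact permutation over 70 assignments; 2 cultures against 2 cannot give a p below 0.333. The 28 gene lists, with 835 symbols of which 4 had no match and 661 were tested, were compared by camera in limma with an estimated correlation, and log2 CPM with a prior count of 2 was used for levels. Interaction terms tested whether strain differences differed between batches 3 and 4 and batches 2 and 6. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 read the tables and drew the plots.

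The tests, the lists, the rule for naming genes and the alternatives were fixed before the data were examined, except for the added ones named here. The rule names fbp, rnb, rnr and pnp, the 10 largest differences in each direction among genes past the threshold with the same sign in all 4 batches, the leading 2 members in each direction of a list described, and the 5 fastest and 5 slowest RNAs in the parent. Over all batches no gene passed in the limma fit of rates or in edgeR at 0 min, the tests the rule was set for, so after the data were seen the rule was applied within batches 3 and 4 and within batches 2 and 6, asking for the same sign in both of those batches. Added after the data were seen were the fits within these batch sets with all their alternatives, the interaction terms, the replicate block within batch sets, rates without the 2 min libraries, and scaling by ssrA and rnpB. The alternatives fixed before were other time windows (0 to 4, 0 to 16, and 4 over 0 min), pseudocounts of 0.1 and 5, no filter and a filter at 50, equal library sums, recomputed spike-in factors (median over spike-ins with at least 100 counts), centring, a joint fit, each culture left out, a preset correlation of 0.01, and the batch as a block.

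The replicate number of the titles, called batch here, is shared by both strains. Same-numbered cultures deviated together from their strain means across genes. The correlations were 0.444, 0.516, 0.276 and 0.460 for rates and 0.701, 0.687, 0.693 and 0.536 for levels in batches 2, 3, 4 and 6. Differently numbered cultures were not compared in this way. Batches 3 and 4 differed as a set from 2 and 6 under both labels, which alone can give such correlations. These correlations therefore do not show that the numbers pair the cultures. Fits with the replicate block called 0 genes slower and 0 faster in decay by limma (308 and 16 at an unadjusted p under 0.05, lowest adjusted p 0.0834). At 0 min they called 0 higher and 0 lower by edgeR (271 and 236 unadjusted, lowest adjusted p 0.257). The fits within batch sets and the interaction terms did not use that block. Blocked fits of them, which leave 1 or 2 residual degrees of freedom per gene, are given as alternatives.

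The fits were tested on simulated data with 50 genes changed by each size among 2962. Each gene was drawn independently, without shifts shared by the genes of a library or of an operon. The recovery, wrong calls and list results below hold for such data only. Over all batches limma recovered 86% of rates changed by -0.3 and 76% of those changed by 0.3 log2 units per min, 6% and 4% at -0.1 and 0.1, with 8 wrong calls. Within batches 3 and 4 it recovered 90% and 66%, and 4% and 2% at -0.1 and 0.1, with 2 wrong calls. For levels over all batches edgeR recovered 72% and 82% of changes by -2 and 2 on the log2 scale and 14% and 20% of changes by -1 and 1, with 5 wrong calls, and DESeq2 88%, 92%, 30% and 46% with 21 wrong calls. Within batches 3 and 4 edgeR recovered 98% to 100%, with 2 wrong calls. With an estimated correlation, camera called a list shifted by 0.3 over all batches (adjusted p 0.000709) but missed it with 2 cultures against 2 (0.283 and 0.301).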

Results

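RNA was followed after rifampicin, an antibiotic that stops new transcription, in cultures of Escherichia coli K-12 MG1655 grown in M9 medium with glucose and casamino acids. The labels name 2 strains, Δrnb Δrnr and Δrnb Δrnr Δfbp, which are called parent and fbp here. The parent lacks rnb and rnr, the genes of the exoribonucleases RNase II and RNase R, and the other strain also lacks fbp, the gene of fructose bisphosphatase, an enzyme of gluconeogenesis. Polynucleotide phosphorylase (PNPase, gene pnp) is another exoribonuclease, which the labels do not name as deleted. The comparison made here is whether RNA decay differs between the 2 labels. Each strain had 4 cultures, numbered 2, 3, 4 and 6 as replicates in the titles. Both strains share these numbers, called batches here. Each culture gave libraries at 0, 2, 4, 8 and 16 min, which makes 40 libraries in 10 groups of 4. Library totals at 0 min were 5350993 to 7061340 reads, and estimated totals over all 40 libraries were 4630029 to 7784899 reads. Transcripts of 4617 genes outside rRNA were counted, and the 2962 that averaged at least 10 RPM (reads scaled to a library sum of 1e+06 over genes outside rRNA) at 0 min were tested.

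The deleted genes were examined first, since they check the labels. In batches 2 and 6 fbp and rnb went with the labels. There fbp (b4232, 4454611 to 4455609 on the chromosome of build ASM584v2) had 214 and 231 RPM at 0 min in the libraries labelled parent, from 1142 and 1203 reads. In the libraries labelled fbp of those batches it had 0.169 and 0.758 RPM, from 1 to 5 reads, where a value of 1 can also stand for no read. Reads of rnb (b1286, 1346978 to 1348912) lay at the lowest value the tables hold, 1, in all 20 libraries of batches 2 and 6. Reads of rnr (b4179, 4406654 to 4409095) were low but present there, at 23.5 to 27.9 RPM from 122 to 182 reads.

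In batches 3 and 4 the deleted genes went against the labels. There fbp had 253 and 254 RPM in the libraries labelled parent and 208 and 210.5 in the libraries labelled fbp. The rnb transcript stood at 405 and 422 RPM in the libraries labelled parent and at 609.9 and 647 in those labelled fbp, from 2617 to 4184 reads. For rnr the values were 225 and 246 against 389 and 391 RPM. The transcript that was low in these batches was pnp (b3164, 3309033 to 3311168), with 44.3 and 49.0 RPM in the libraries labelled fbp, from 261 to 336 reads. It had 1795 and 1800.1 in the libraries labelled parent of the same batches and 2432 to 3030.2 in the 4 libraries of batches 2 and 6. Strain names below are therefore the labels, not established genotypes. Each comparison is given over all 8 cultures, as designed, and then within batches 2 and 6 and within batches 3 and 4. That division by replicate number was made after the deleted genes had been seen.

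**Figure D1:**
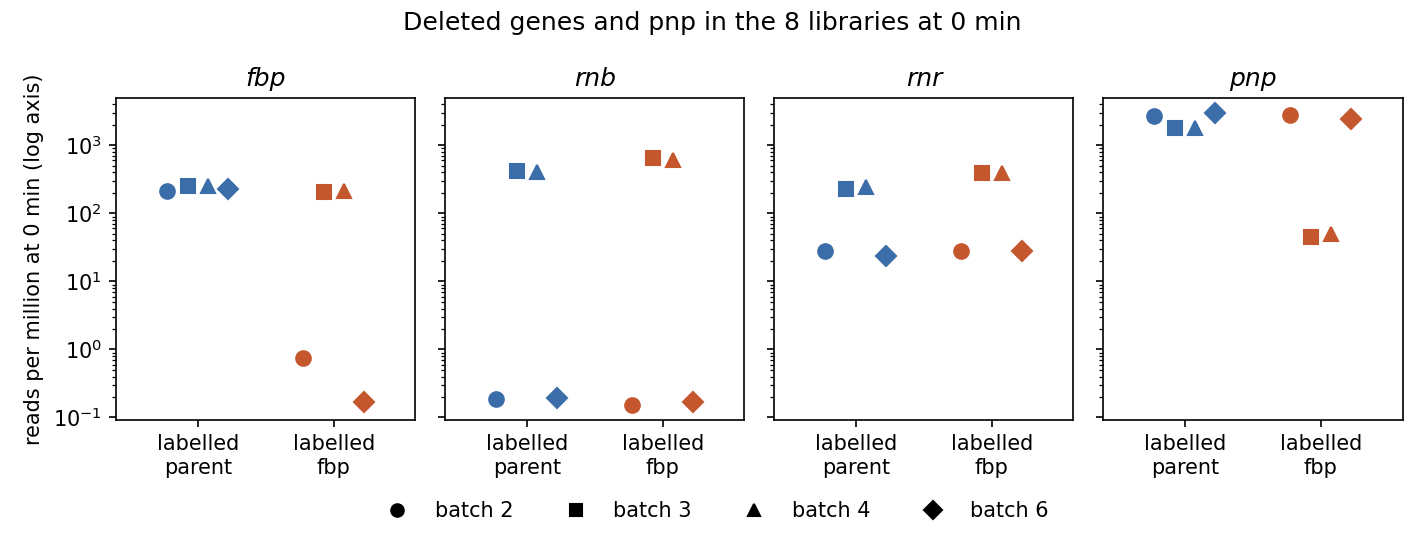
Reads RPM at 0 min (log axis) of fbp, rnb, rnr and pnp in the 8 cultures, with blue points for libraries labelled parent, orange points for libraries labelled fbp and one marker shape per batch. In batches 3 and 4 rnb lies at 405 to 647 RPM under both labels, and pnp lies at 44.3 and 49.0 in the libraries labelled fbp.

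How much RNA was left after rifampicin was compared first. In the cultures labelled parent the median gene had 38.0% ± 6.71 (SD, n = 4) of its 0 min value at 2 min, 12.0% ± 1.92 at 4 min and 3.03% ± 0.684 at 8 min. In the cultures labelled fbp the same times gave 45.2% ± 22.2, 18.4% ± 8.34 and 5.32% ± 2.60. The sum over genes was larger, with 30.4% ± 3.95 left at 8 min under the label parent and 35.5% ± 11.5 under the label fbp. Stable RNAs hold part of that sum: ssrA, the transfer-messenger RNA that frees stalled ribosomes, made up 8.02% of the 0 min libraries and kept 52.3% to 97.4% of its value at 16 min over the 8 cultures. The mRNA of lpp, a major outer membrane lipoprotein, kept 49.3% to 123%. The strain difference of the sum was 4.39 points at 2 min, 8.17 at 4 min, 5.07 at 8 min and 4.48 at 16 min, all smaller than the spread between the cultures labelled fbp. Without the culture labelled fbp of batch 3 the last 3 of these fell to 0.269, 0.399 and 1.71 points, so they rested largely on that culture. Exact permutation tests over the 70 assignments (two-sided) gave p of 0.8, 0.486, 0.514 and 0.286, or 0.8 and 3 times 0.686 after Benjamini-Hochberg adjustment over the 4 times. Those of the median gene gave 0.743, 0.2, 0.171 and 0.286, adjusted to 0.743 at 2 min and 0.381 later. The smallest p that 4 cultures against 4 can give is 0.0286.

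The batches differed in direction. At 8 min the sum was 30.0% to 36.1% in the cultures labelled parent and 25.4% to 26.8% in those labelled fbp of batches 2 and 6, but 27.5% to 28.0% and 40.2% to 49.5% in batches 3 and 4. The within-batch differences of the sum in batches 2, 3, 4 and 6 were -23.6, 8.39, -3.67 and 36.5 points at 2 min, -10.9, 33.8, 12.6 and -2.87 at 4 min, -10.7, 21.5, 12.7 and -3.23 at 8 min, and -2.29, 11.1, 4.65 and 4.42 at 16 min. The culture labelled fbp of batch 6 stood apart at 2 min: its sum was 102% of 0 min, its median gene 76.6%, and the stable RNAs rnpB (RNase P) and ssrS (6S RNA) were at 141% and 163%. Without it the 2 min difference was -5.71 points. The culture labelled fbp of batch 3 was high at 4 min, with a sum of 81.3% after 74.4% at 2 min, and ssrA, rnpB, ssrS and lpp at 142%, 153%, 250% and 162% of 0 min. At 8 min the same culture had ssrA, rnpB, ssrS and lpp at 114%, 151%, 273% and 165%. Its spike-in totals were 181807 at 0 min, 230906 at 4 min and 238875 at 8 min. Both the 4 min and the 8 min library enter the rates of batches 3 and 4 below.

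**Figure D2:**
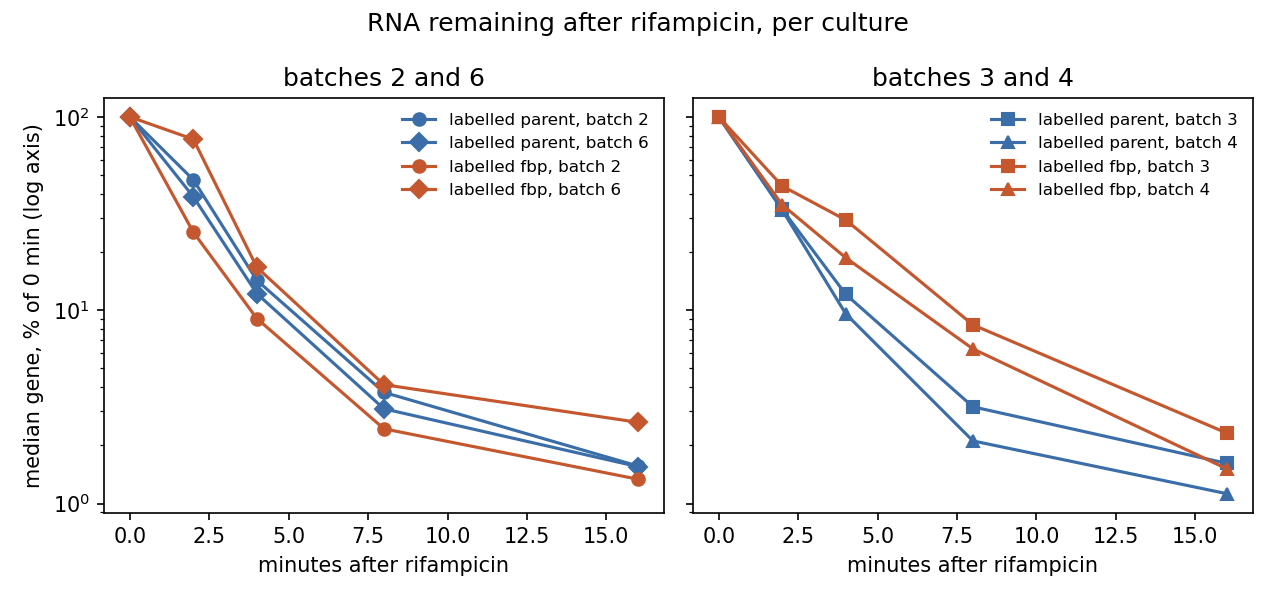
Median gene's remaining RNA, in percent of the 0 min value (log axis), against minutes after rifampicin, with one line per culture, batches 2 and 6 on the left and 3 and 4 on the right. At 8 min the cultures labelled fbp of batches 3 and 4 kept 6.31% and 8.40%, and the other 6 kept 2.11% to 4.12%.

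Decay rates summarised each culture over 0 to 8 min. The median gene lost 0.491 ± 0.0194 (SD, n = 4) log2 units per min in the cultures labelled parent and 0.451 ± 0.0565 in those labelled fbp, a difference of -0.0402 (exact permutation test, two-sided, p = 0.314). Leaving out 1 culture at a time gave -0.0592 to -0.0183, the smallest without the culture labelled fbp of batch 3 (exact permutation p = 0.514). The corresponding half-lives were 2.04 ± 0.0778 and 2.24 ± 0.288 min (n = 4, exact permutation p = 0.314). Within batches 2, 3, 4 and 6 the rate differed by 0.0329, -0.0986, -0.0953 and 0.000131, so the pooled difference in rates over 0 to 8 min did not hold within each batch. In batches 3 and 4 the half-lives were 2.07 and 1.92 min under the label parent and 2.59 and 2.36 min under the label fbp; in batches 2 and 6 they were 2.10 and 2.05 min against 1.97 and 2.05 min. The authors' deposited half-lives, fitted over 0 to 16 min, had medians over the same 2962 genes of 2.62, 2.77, 2.59 and 2.54 min for the cultures labelled parent of batches 2, 3, 4 and 6 and 2.72, 2.91, 2.75 and 2.60 min for those labelled fbp. They were longer under the label fbp in all 4 batches, a difference that was not tested.

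Nearly every tested RNA decayed under both labels. The fastest in the cultures labelled parent were gadX, a regulator of acid resistance, at 0.907 ± 0.0430 log2 units per min (SD, n = 4, half-life 1.10 min), and mtr, a tryptophan transporter, at 0.885 ± 0.0505 (1.13 min). The sensor kinase gene evgS followed at 0.863 ± 0.0465, the cell wall hydrolase gene mepS at 0.857 ± 0.0591 and the lipopolysaccharide transport gene lptD at 0.854 ± 0.0641. At the other end lay ffs, the RNA of the signal recognition particle, at -0.0887 ± 0.0189, and ssrS at -0.0833 ± 0.0410, with 170% of its 0 min value at 16 min. The mRNA of ugd (UDP-glucose dehydrogenase) came next at -0.0789 ± 0.0862, standing at 395% of its 0 min value at 4 min and 35.2% at 16 min. Values for the toxin gene ldrD were -0.0746 ± 0.0328 and for the small RNA ryfD -0.0703 ± 0.0281. In the limma test of each rate against 0 (Benjamini-Hochberg, two-sided), 2913 of 2962 genes (98.3%) decayed under the label parent, 2 rose and 47 did not pass; under the label fbp 2884 (97.4%) decayed, 5 rose and 73 did not pass. The 6 genes that rose under either label were ffs, ssrS, zntR, ldrD, ryfD and mgrR, named after their values were seen, and all are on a scale set by the spike-ins.

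Gene by gene, over all 8 cultures, no decay difference between the labels passed. The glycolytic mRNA of pgk (phosphoglycerate kinase, b2926) had a mean difference, label fbp less label parent, of -0.160 log2 units per min (SE 0.104, n = 4 against 4), but batches 2, 3, 4 and 6 gave 0.0594, -0.332, -0.433 and 0.0640. That of eno (enolase, b2779) gave -0.115 (SE 0.0791), with 0.0555, -0.296, -0.321 and 0.103 in those batches. The small RNA csrB, which binds the regulator CsrA, gave -0.335 (SE 0.131), with 0.0392, -0.665, -0.703 and -0.0122. By limma (two-sided, Benjamini-Hochberg), 0 genes were slower and 0 faster, the lowest adjusted p was 0.590, and at an unadjusted p under 0.05 there were 207 slower and 10 faster. A joint limma fit over single libraries called 1 gene, fbp itself. Of the 28 gene lists, camera with an estimated correlation called 0 (lowest adjusted p 0.950, 1 list at an unadjusted p under 0.05), and with the correlation preset at 0.01 it called 6, none of which hold with an estimated correlation. For glycolysis, where no member passed over all batches or adjusted over the list alone, the median difference of the 14 tested members was -0.0786 over all batches, 0.0638 in batches 2 and 6 and -0.223 in batches 3 and 4.

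Within batches 2 and 6, whose fbp and rnb reads went with the labels, none of the 14 glycolytic, 19 citrate cycle and 54 ribosomal protein mRNAs tested differed detectably in decay between the labels, also adjusted over the list alone. The values for pgk were 0.618 log2 units per min in the libraries labelled parent and 0.680 in those labelled fbp, a difference of 0.0617 (SE 0.0393, n = 2 against 2). For eno they were 0.368 and 0.447, a difference of 0.0792 (SE 0.0432), and for pnp 0.646 and 0.690, a difference of 0.0442 (SE 0.0451). The rates under the label fbp include the 2 min library of batch 6, where the sum stood at 102% of 0 min and the median gene at 76.6%. The only gene past limma's Benjamini-Hochberg adjusted p of 0.05 (two-sided) was fbp (-0.557, adjusted p 0.000508), which had 1 to 5 reads in the libraries labelled fbp and so has no true rate there. No gene was called faster, and at an unadjusted p under 0.05 limma had 39 slower and 156 faster. Without the culture labelled fbp of batch 2 it called 163 slower and 108 faster. In the 28 lists, camera with an estimated correlation called 0 (lowest adjusted p 0.489, 0 at an unadjusted p under 0.05) and 18 with the preset correlation. With an estimated correlation it missed a list shifted by 0.3 in simulated data of these batches (adjusted p 0.283). Simulated data with 2 cultures against 2 of these batches drew each gene independently, without shifts shared by a library. There 72% of 50 genes slowed by 0.3 log2 units per min were recovered, and 44% of 50 sped up by 0.3. Of those changed by 0.1 it was 0%.

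Within batches 3 and 4, many RNAs decayed more slowly in the libraries labelled fbp, which held fbp, rnb and rnr reads and few pnp reads. Here csrB (b4408, 2924156 to 2924524) fell at 0.634 log2 units per min in the libraries labelled parent and did not fall in those labelled fbp, at -0.0498 (difference -0.684, SE 0.0335, n = 2 against 2). At 16 min 124% and 85.5% of csrB were left in the 2 cultures labelled fbp, against 1.62% to 3.15% in the other 6 cultures of the series. The mRNA of surA, a periplasmic chaperone (b0053, 53416 to 54702), went from 0.793 to 0.134 (-0.659, SE 0.0507), that of sapA, a peptide transport protein (b1294), from 0.656 to 0.0338, and that of holA, a DNA polymerase subunit (b0640), from 0.678 to 0.0587. For lptA (lipopolysaccharide transport, b3200) the rates were 0.655 and 0.0647, for asnA (asparagine synthetase, b3744) 0.707 and 0.138, and for yagN (a prophage gene, b0280) 0.597 and 0.0481. The cell division gene ftsE (b3463) went from 0.701 to 0.185 and the tRNA-modifying enzyme gene tmcA (b2474) from 0.652 to 0.140. The tRNA gene valU (b2401) gave 0.515 and 0.00639, which is uncertain because near-identical tRNA copies share reads.

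Faster decay in the libraries labelled fbp of these batches was found for fewer genes. The small protein genes ytiD (b4721, 4556654 to 4556797), idlP (b4722) and yicU (b4797) went from 0.164 to 0.548, from 0.251 to 0.619 and from 0.184 to 0.520 log2 units per min. The copper efflux gene cusC (b0572) went from 0.127 to 0.443, but ytiD and cusC had under 4 CPM (counts scaled to 1e+06 with edgeR's TMM factors) in the libraries labelled parent at 0 min, where the pseudocount of 1 lowers a rate. The regulator gene lrhA (b2289) went from 0.221 to 0.478, the cold shock family gene cspE (b0623) from 0.319 to 0.540 and the sulfate permease gene cysU (b2424) from 0.439 to 0.647. The tRNA gene glyY (b4165, also a repeated tRNA) gave 0.301 and 0.492, the branched-chain amino acid transport gene livK (b3458) 0.355 and 0.545, and the regulator gene tdcA (b3118) 0.267 and 0.450. When rates came from 0 to 4 min the calls of cspE (0.183), cysU (0.136) and livK (0.0291) were lost, cspE at a size near that over 0 to 8 min, and tdcA then had the opposite sign, -0.196. With a pseudocount of 0.1 cysU (-0.0283) and tdcA (-0.00182) had the opposite sign and the call of livK (0.0170) was lost.

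By limma (two-sided, Benjamini-Hochberg, n = 2 against 2), 1518 of the 2962 genes were slower and 75 faster in the libraries labelled fbp of batches 3 and 4, so 95.3% of the calls were slower, and adjusted p was 2.49e-86 for csrB, 2.38e-35 for surA and 8.12e-36 for ytiD. The SE and adjusted p of decay within these batches rest on a spread that limma pooled over genes of like level. The mannose permease gene manZ, with parent-label rates of 0.109 and 0.106, and prfC, with 0.701 and 0.840, both had an SE of 0.0517. Such p values hardly measure a gene's own spread and do not allow for a shift shared by all genes of a culture. The median difference over all genes was -0.0964. In simulated data of these batches, with genes drawn independently, 90% of rates changed by -0.3 were recovered, at a median estimate of -0.268. Of those changed by 0.3 it was 66%, at 0.201, so slower and faster changes of equal size were not called equally. The balance of slower and faster calls also depended on the time window, the pseudocount and the scaling between time points. Over 0 to 16 min there were 574 slower and 526 faster and over 0 to 4 min 1187 and 11, and pseudocounts of 0.1 and 5 gave 1614 and 24, and 1371 and 254. With the replicate block there were 1948 slower and 105 faster. Slower and faster calls numbered 1225 and 122 with recomputed spike-in factors, 947 and 143 when ssrA and rnpB set the scale, 652 and 121 with equal library sums, and 742 and 566 when each culture was centred on its median. Without the culture labelled parent of batch 4 limma called 827 slower and without the culture labelled fbp of batch 3 it called 848. Of the 75 faster genes 14 had under 10 CPM in the libraries labelled parent, and the median of the 75 there was 17.8 CPM. A low level under the label fbp lowers a rate in the same way, and how many slower calls this touches was not counted. None of the 20 genes named above passed in batches 2 and 6 (adjusted p 0.596 or more by limma), and for all 20 the difference between the batch sets passed itself, as it did for 1177 genes in all.

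**Figure D3:**
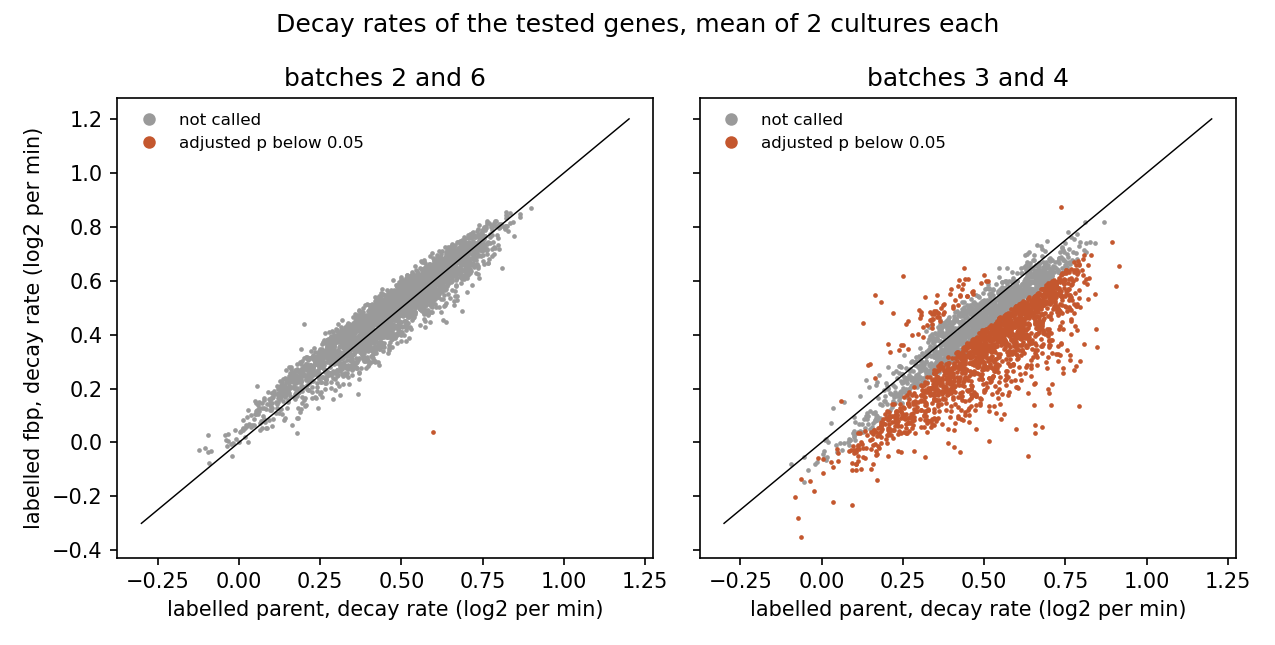
Decay rate in the libraries labelled fbp against that in the libraries labelled parent (both log2 units per min, mean of 2 cultures), with one point per tested gene, batches 2 and 6 in one panel and 3 and 4 in the other. Orange points passed an adjusted p of 0.05 and the line marks equal rates; 1 gene passed in batches 2 and 6 and 1593 in batches 3 and 4.

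Metabolic genes of batches 3 and 4 are given by list, to be read beside the 1518 slower of all 2962 genes. There camera with an estimated correlation called 0 of 28 lists (Benjamini-Hochberg adjusted p 0.995 for each of these, 0 at an unadjusted p under 0.05). In simulated data of these batches it missed a list shifted by 0.3 log2 units per min (adjusted p 0.301). The 0 calls therefore do not show that the lists moved with all genes. In glycolysis 12 of 14 mRNAs were slower and 2 did not pass (12 slower adjusted over the list alone), and each of the 4 other scalings left 8 to 11 slower. The half-life of pgk went from 1.81 and 1.48 min in the libraries labelled parent to 4.52 and 4.11 min in those labelled fbp (-0.382, SE 0.0450), and that of eno from 2.49 and 2.20 to 9.40 and 7.52 min (-0.308, SE 0.0367). In gluconeogenesis 5 of 6 were slower, fbp among them (5 adjusted over the list alone), led by the malic enzyme genes maeA (-0.285) and maeB (-0.262). In the citrate cycle 16 of 19 were slower (16 adjusted over the list alone), but 6 with equal library sums. There the citrate synthase gene gltA changed by -0.373 and the half-life of icd (isocitrate dehydrogenase) went from 3.02 and 2.68 to 13.7 and 9.97 min. With rates over 0 to 16 min pgk, maeA and gltA no longer passed (limma, Benjamini-Hochberg adjusted p 0.437, 0.0964 and 0.0817).

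Sugar uptake and side routes of those batches are given in the same way. Of 11 genes of the pentose phosphate and Entner-Doudoroff routes 9 were slower (10 adjusted over the list alone), led by tktA (-0.202) and talB (-0.187), but 2 were slower and 1 faster with equal library sums. Of 9 genes of glucose uptake by the phosphotransferase system 5 were slower (5 adjusted over the list alone), led by the mannose permease genes manZ (-0.188) and manY (-0.182), but 0 were slower and 1 faster by limma with equal library sums. Of 12 genes of acetate metabolism and fermentation 8 were slower (9 adjusted over the list alone), led by adhE (-0.229) and pflB (-0.201), or 3 with equal library sums. Of 22 genes of carbon catabolism activated by CRP 19 were slower (19 adjusted over the list alone), led by gatY (-0.397) and galK (-0.325), or 9 with equal library sums. Over 0 to 16 min tktA (-0.0256), talB (-0.0307), manZ (-0.0270), manY (-0.0396), pflB (-0.0150) and galK (-0.0266) lost their calls, and adhE (0.0843) was faster. Calls were also lost for manZ (-0.0945) and manY (-0.0884) with equal library sums, and for pflB over 0 to 4 min at nearly the same size (-0.186).

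Genes of stress and biosynthesis were slower in shares to be read beside the 1518 of all 2962 genes, and camera with an estimated correlation called none of these lists (Benjamini-Hochberg adjusted p 0.995 each, 0 of 28 lists at an unadjusted p under 0.05). Of 28 genes of the general stress response, under the sigma factor RpoS, 19 were slower (20 adjusted over the list alone), led by the acid resistance genes hdeB (-0.340) and gadE (-0.343), and with equal library sums 6 were slower and 1 faster. Of 73 amino acid synthesis genes 37 were slower (37 adjusted over the list alone), led by asnA and the tryptophan synthesis gene trpE (-0.499); centring gave 21 slower and 12 faster. Of 30 nucleotide synthesis genes 16 were slower and 1 faster (16 and 1 adjusted over the list alone), or 10 and 8 when centred. The purine genes purF (-0.457) and purC (-0.282) were slower and the carbamoyl phosphate gene carB (0.0970) faster. By limma carB lost its call over 0 to 16 min (0.0263, Benjamini-Hochberg adjusted p 0.483). The calls of purC over 0 to 4 min (-0.238, adjusted p 0.0510) and of gadE with equal library sums (-0.261, adjusted p 0.0560) were also lost, at sizes near those above.

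Ribosomal protein and small RNA genes moved both ways in those batches. Of 54 ribosomal protein mRNAs 12 were slower and 9 faster (11 and 9 adjusted over the list alone), and the balance flipped to 1 slower and 19 faster with equal library sums and 6 and 31 when centred. Here rplN (-0.346) and rplE (-0.212) were slower, rplB (0.152) and rpsA (0.112) faster; rplE lost its call over 0 to 16 min (-0.00689) and with equal library sums (-0.120). The calls of rplB (0.115) and rpsA (0.0832) were lost over 0 to 4 min, where most of the difference remained. Among 19 small regulatory RNAs 9 were slower and 4 faster (9 and 5 adjusted over the list alone), and the median of -0.0604 turned to 0.0304 with equal library sums and 0.0365 when centred. The half-life of csrC, which like csrB binds CsrA, went from 2.09 and 1.81 to 12.1 and 6.79 min, and ryjB (0.117) and sraB (0.116) were faster. Over 0 to 4 min the calls of ryjB (0.1002) and sraB (0.0671) were lost, as was that of ryjB with a pseudocount of 0.1 (0.101). Of 20 flagella and chemotaxis mRNAs 5 were faster, led by fliF (0.134) and fliL (0.122), and 2 slower, tsr (-0.205) and flgK (-0.116), with 5 and 2 adjusted over the list alone, and 13 faster and 1 slower when centred. The call of tsr was lost over 0 to 4 min at nearly the same size (-0.198), that of fliF with a pseudocount of 0.1 (0.0515), that of fliL with equal library sums (0.0660), and that of flgK with equal library sums, centring, scaling by ssrA and rnpB and a pseudocount of 5. Over 0 to 16 min flgK had the opposite sign (0.0159), and over 0 to 4 min fliF (-0.00772) and fliL (-0.281) had the opposite sign, as fliL did with a pseudocount of 0.1 (-0.0847). Among 26 genes of RNases and their partners 14 were slower (18 adjusted over the list alone), 7 with equal library sums and 8, with 1 faster, when centred. One of them, pnp, went from half-lives of 1.58 and 1.33 to 3.80 and 3.44 min. Under the label fbp this rests on residual reads, 261 to 336 at 0 min, at most 2.73% of the level under the label parent. Whether they come from intact mRNA was not tested. The rnt (RNase T) mRNA changed by -0.293, a call lost over 0 to 16 min (-0.00495). With an estimated correlation camera called 0 of the 28 lists in batches 3 and 4 (Benjamini-Hochberg adjusted p 0.995 for each of these lists, 0 at an unadjusted p under 0.05). With the preset correlation it called 5. The setting with an estimated correlation missed a shifted list in simulated data of these batches.

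Transcript levels before rifampicin were compared at 0 min. Over all 8 libraries, surA and pnp did not pass in edgeR: surA differed by 1.32 on the log2 scale (SE 0.39, n = 4 against 4) and pnp by -0.72 (SE 1.21). In edgeR's quasi-likelihood test (two-sided, Benjamini-Hochberg), 0 genes were higher and 0 lower in the libraries labelled fbp, with a lowest adjusted p of 0.339 and 217 higher and 123 lower at an unadjusted p under 0.05. DESeq2 called 59 higher and 24 lower, surA among the higher (adjusted p 0.0465, Benjamini-Hochberg), and 70 of these 83 had the same sign in all 4 batches. Genes picked for a pooled difference tend to share a sign, and the share over all tested genes was not computed. The difference of surA was 0.242 and 0.294 in batches 2 and 6 but 1.92 and 1.98 in batches 3 and 4. For tabA, also called, it was 3.35 and 3.26 against 0.251 and 0.276. Without the culture labelled fbp of batch 6 edgeR called 6 higher and 10 lower. Camera with an estimated correlation called 0 of 28 lists (lowest adjusted p 0.678, 1 at an unadjusted p under 0.05), and 6 with the preset correlation.

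In batches 2 and 6 the gene that rose was tabA, which encodes a protein tied to biofilm formation (b4252, 4474862 to 4475314). It had 24.1 and 28.7 CPM in the libraries labelled parent and 249 and 277 in those labelled fbp, a log2 difference of 3.30 (SE 0.23, n = 2 against 2). The other call was fbp, at -8.78, a fitted value that rests on 1 to 5 reads in the libraries labelled fbp. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (two-sided), adjusted p was 0.0321 for tabA and 0.0120 for fbp, and at an unadjusted p under 0.05 there were 18 higher and 39 lower. With equal library sums tabA no longer passed (3.24, adjusted p 0.0520 by edgeR; range over its alternatives 4.52e-17 to 0.0520), and DESeq2 added its neighbour yjgL (2.31, adjusted p 0.0153, Benjamini-Hochberg). Without the culture labelled fbp of batch 2 edgeR called 4 higher and 92 lower, and without the culture labelled parent of batch 6 it called 0 higher. Camera with an estimated correlation called 0 of 28 lists (lowest adjusted p 0.730, 0 at an unadjusted p under 0.05), and 10 with the preset correlation. Its power for levels was not simulated. In simulated data of these batches 90% and 82% of genes raised or lowered by 2 on the log2 scale were recovered by edgeR, but 12% of those changed by 1.

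The 10 largest rises at 0 min in the libraries labelled fbp of batches 3 and 4 are given gene by gene. The sulfate-binding protein gene sbp (b3917, 4108834 to 4109823) went from 23.3 and 23.3 CPM in the libraries labelled parent to 1669 and 1699.7 in those labelled fbp, a log2 difference of 6.24 (SE 0.07, n = 2 against 2), 75.7-fold. The sulfate activation genes cysC (b2750), cysN (b2751) and cysD (b2752) rose by 5.73, 5.71 and 5.10, with cysC and cysN sharing 1 base of sequence. The sulfite and phosphosulfate reductase genes cysI (b2763) and cysH (b2762) rose by 5.37 and 5.30, and the sulfate transport genes cysW (b2423) and cysA (b2422) by 5.09 and 4.89. The remaining members of the 10 largest rises were ytiD (6.73, from 2.21 and 3.11 to 264 and 279 CPM) and cusC (5.05, from 2.05 and 1.56 to 61.2 and 53.7).

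The largest fall in these batches was that of pnp, from 1807 and 1811 CPM in the libraries labelled parent to 40.01 and 43.8 in those labelled fbp, or -5.36 (SE 0.07). Next came glnK, a regulator of ammonium transport (b0450), at -3.66, from 19.4 and 22.1 to 0.766 and 2.22 CPM, and katE, a catalase of stationary phase (b1732), at -3.17, from 237 and 247 to 25.6 and 25.6. The small RNA csrC (b4457) fell from 12877 and 12359 to 1305 and 1591 CPM, -3.05. The hydrolase gene ycaC (b0897) went from 298 and 288 to 36.9 and 33.0 CPM. The regulator gene yiaG (b3555), the arginine catabolism gene astC (b1748) and the ribosome-associated protein gene sra (b1480) differed by -2.99, -2.97 and -2.87. The acid chaperone genes hdeA (b3510) and hdeB (b3509) differed by -2.78 and -2.76, hdeA going from 5115 and 5103 to 715 and 699 CPM.

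By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (two-sided, n = 2 against 2), 1049 genes were higher and 1047 lower in the libraries labelled fbp of batches 3 and 4, 70.8% of those tested, and the 20 named genes had adjusted p from 1.37e-22 (sbp) to 6.11e-09 (astC). DESeq2 called 806 higher and 917 lower, and edgeR with the replicate block 1100 and 1071. Cultures 3 and 4 were far more alike at 0 min than cultures 2 and 6. Chi-square per degree of freedom over genes was 3.95 under the label parent and 8.49 under the label fbp (r of log2 CPM 0.997 and 0.996), against 63.4 and 161 (r 0.982 and 0.949) for cultures 2 and 6. A difference of a given size therefore passed more readily in batches 3 and 4, and the numbers of calls in the batch sets do not compare the sizes of effects. None of the 20 passed in batches 2 and 6 (adjusted p 0.986 or more by edgeR); there sbp differed by -0.56, cysN by 0.21 and pnp by -0.06. The strain difference itself differed between the batch sets for 291 genes. These libraries go against their labels, so the direction is that of the labels and is not assigned to a loss of fbp.

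**Figure D4:**
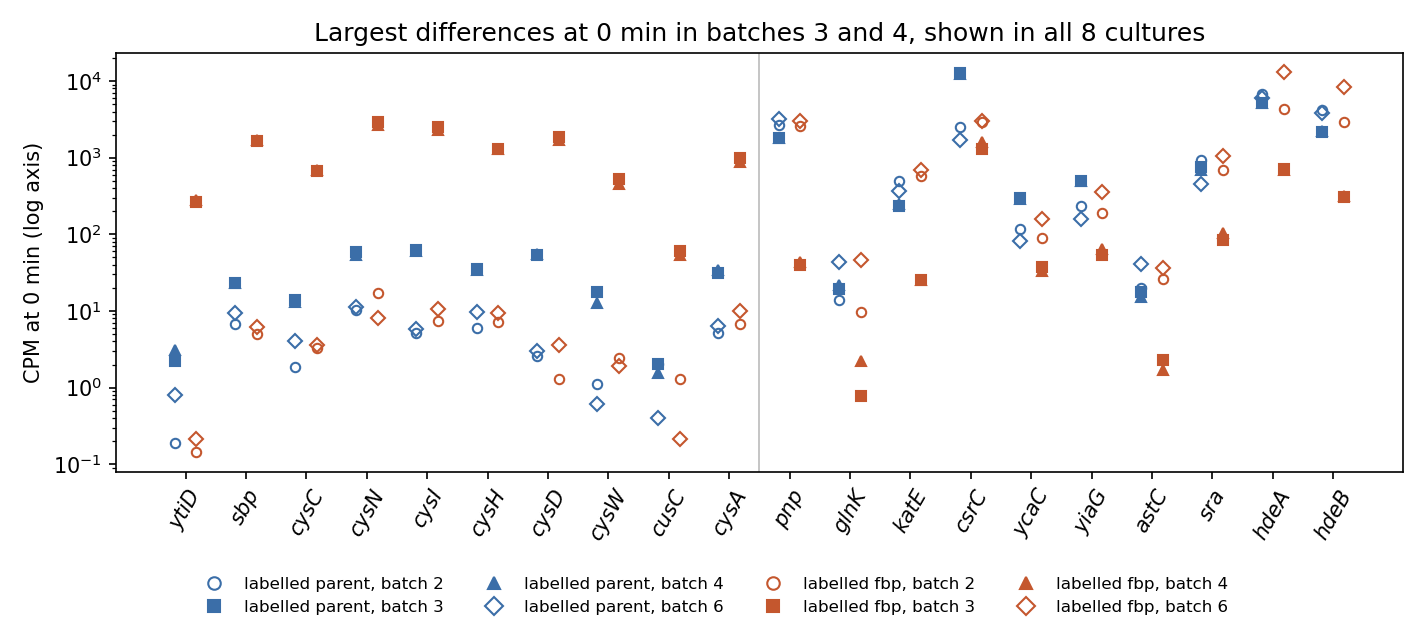
Counts at 0 min in CPM, scaled with edgeR's TMM factors (log axis) of the 20 genes with the largest rises and falls in batches 3 and 4, in all 8 cultures, blue for libraries labelled parent and orange for those labelled fbp, filled for batches 3 and 4 and open for batches 2 and 6. In the filled points sbp goes from 23.3 to 1669 and 1699.7, and pnp from 1807 and 1811 to 40.01 and 43.8.

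Among gene families, those of the general stress response, under the sigma factor RpoS, were lower in the libraries labelled fbp of batches 3 and 4: 27 of 28 fell and 1 did not pass (27 adjusted over the list alone), led by hdeA and hdeB, with a median of -1.91. Under each of the 4 other scalings and tools tried 27 of them were lower. Of 54 ribosomal protein mRNAs 47 were lower and 7 did not pass (47 adjusted over the list alone), led by rpsU (-1.44, from 1163 and 1190.0 to 404 and 424 CPM) and rpsT (-1.22); without rescaling 25 were lower. Of 20 flagella and chemotaxis genes 16 were higher and 1 lower (17 and 1 adjusted over the list alone), led by fliL (2.36) and the flagellar sigma factor gene fliA (1.49), while the flagellin gene fliC was lower (-0.45). Of 73 amino acid synthesis genes 48 were higher and 15 lower (48 and 16 adjusted over the list alone), with the cysteine synthase genes cysK (3.12) and cysM (3.91) on one side and the glutamine synthetase gene glnA (-1.83) and aroH (-1.41) on the other. In glycolysis 5 were higher and 6 lower (5 and 6 adjusted over the list alone), or 2 higher and 4 lower without rescaling. The median of -0.02 turned positive (0.07) with equal library sums. The aldolase genes fbaB (-2.47) and fbaA (-0.92) were lower, glk (0.58) and gpmM (0.25) higher. With an estimated correlation camera called 0 of 28 lists (2 at an unadjusted p under 0.05): the Benjamini-Hochberg adjusted p was 0.448 for the stress genes, 0.457 for flagella, 0.754 for ribosomal proteins and 0.814 for amino acid synthesis and for glycolysis. With the preset correlation 10 lists were called. With 2 cultures against 2, camera with an estimated correlation missed a shifted list in simulated decay rates. Its power for levels was not simulated, so 0 calls do not show that these lists stayed the same.

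Counts for the other lists at 0 min in batches 3 and 4 stand beside 70.8% of all tested genes called. Of 30 nucleotide synthesis genes 25 were lower and 3 higher in the libraries labelled fbp (25 and 3 adjusted over the list alone), with pyrC (-1.51) and ndk (-1.34) lower and purL (0.48) and purM (0.38) higher. In the citrate cycle 12 of 19 were lower and 4 higher (12 and 4 adjusted over the list alone), with the malate synthase gene aceB (-1.34) and icd (-0.80) lower and the aconitase gene acnB (0.50) and the fumarase gene fumB (0.76) higher. Of 19 small regulatory RNAs 10 were higher and 3 lower (10 and 3 adjusted over the list alone), with glmY (2.54) and glmZ (1.62), which act on glucosamine synthesis, higher and csrC and mgrR (-1.15) lower. In gluconeogenesis 3 of 6 were higher and 1, fbp, lower (3 and 1 adjusted over the list alone), with pck (0.41) and maeB (0.40) higher. Without rescaling 3 were higher and 0 lower, so the lower call was lost. Among genes of RNases and their partners 10 of 26 were higher and 8 lower (10 and 8 adjusted over the list alone), with the RNase inhibitor gene rraA (0.79) and rnt (0.79) higher and pnp and rraB (-1.06) lower; DESeq2 turned this balance to 6 and 8. With an estimated correlation camera's Benjamini-Hochberg adjusted p was 0.814 for each of these lists except the RNases, at 0.990. Here too such values do not show that the lists stayed the same.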

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

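Every test below of an explanation, and the fits within batch sets, were chosen only after the result was seen.

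Both strains should lack rnb, yet every culture of batches 3 and 4 had it. There the interaction of label and batch set passed for 1177 genes in decay rate by limma (1142 lower, 35 higher in batches 3 and 4) and for 291 in level at 0 min by edgeR (112 higher, 179 lower). With the replicate block these were 1595 and 211. Those were brought up because the same contrast gave different effects in the 2 batch sets. The label difference in median decay rate in batches 3 and 4 less that in batches 2 and 6 was -0.113 log2 units per min, and the sum remaining differed by 30.1 points more at 4 min and 24.1 points more at 8 min. These last 3 differences were not tested; they were brought up because both batches of one set moved one way and both of the other the opposite way.

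For the reads of rnb, fbp and rnr in batches 3 and 4, the tables argue against several explanations. A swap between the parent and fbp cultures would leave rnb at the floor, but its lowest 0 min value there was 2617 reads. Paralog reads would raise rnb elsewhere too, but its highest value in the 20 libraries of batches 2 and 6 was 0.192 RPM. A minor share of another strain's RNA in the libraries labelled fbp would leave most of pnp, but its highest value was 2.01% of the lowest in those of batches 2 and 6. Both labels name rnb as deleted, yet it had 2617 to 4184 reads at 0 min in the cultures of batches 3 and 4. In RPM it lay at least 2105 times above its highest value in batches 2 and 6, where that value is the floor. These values argue against RNA of the named strains alone in batches 3 and 4. Cultures of other strains than the labels name remain a candidate explanation. A mixture in the libraries labelled parent was not tested.

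For the slower decay in the libraries labelled fbp of batches 3 and 4, a loss of fbp transcripts was argued against, since fbp kept at least 81.9% of its level under the label parent. Normalization to spike-ins was argued against as the whole cause only by the scalings without spike-ins. With equal library sums 652 genes were slower, and the median difference over all genes was -0.0445 log2 units per min. Scaled by ssrA and rnpB that median was -0.0533, against -0.0964 as deposited. Recomputed spike-in factors still rest on the spike-ins, and centring removes a shared shift by construction, so neither can decide this. The calls do not allow for a shift shared by all genes of a culture. A loss of pnp may take part: 1518 genes, csrB and surA among them, were slower by limma (adjusted p under 0.05, Benjamini-Hochberg) where pnp stood at no more than 2.73% of its level under the label parent. That share and the label were confounded in these 2 cultures, so pnp cannot be told apart from any other difference between them. A biological effect of the named fbp deletion was testable only in batches 2 and 6. It is open for differences too small for 2 cultures against 2 to show. In simulated data of those batches, with genes drawn independently, limma recovered 72% and 44% of rates changed by -0.3 and 0.3. None of those changed by 0.1 were recovered.

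The 8 cultures were also split into 4 and 4 in all other ways. For decay the real split called 0 genes by limma (217 at an unadjusted p under 0.05), the highest other 150, and 35 of 35 splits gave at least as many as the real one, which a real count of 0 fixes in advance. For levels the real split called 0 by edgeR (340 unadjusted), the highest other 680, again 35 of 35 by the same construction, and for the lists the real count and the highest other were 0 for decay and 0 for levels with camera, with 35 of 35 each. These 4 counts therefore decide nothing about chance. The split with 150 and 680 calls set batches 2 and 6 against 3 and 4, which points to a structure of the samples. Of the splits 8 part all 4 same-numbered pairs, as the real one does.

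Single cultures stood far from the other 3 of their group in 2 of 36 groups, where chance gives about 1 in 20. At 2 min the sum remaining in the culture labelled parent of batch 2 was 74.0%, against 65.0% to 66.1% in the others. At 16 min the median gene in the culture labelled parent of batch 4 had 1.12% left, against 1.55% to 1.61%. No explanation was tested for these.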

How the results depend on the processing

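Fits within batch sets, rates without the 2 min libraries and scaling by ssrA and rnpB were chosen only after the data were seen. Unless said otherwise the cause was not tested.

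Of the main results, 285 values stayed the same (counts within 1.5 times, other values by call, sign or spread between cultures), 53 moved and 4 reversed. Of named genes 843 stayed the same, 33 moved, 47 lost and 5 gained a call, and 12 reversed. The median rate difference ranged from -0.116 to 0.0165 and reversed with batches 2 and 6 only (0.0165, exact permutation p 0.333). The sum remaining reversed there at 4 min (-6.87) and 8 min (-6.96). Leaving out 1 culture at a time gave -5.71 to 11.7 at 2 min, the lowest without the culture labelled fbp of batch 6, and 0.269 to 14.0 at 4 min, 0.399 to 8.43 at 8 min and 1.71 to 6.06 at 16 min, the lowest without the culture labelled fbp of batch 3. Without that culture the median rate difference was -0.0183. Over all batches the replicate block changed no call. Within batches 3 and 4, where it was added after the data were seen, it gave 1948 slower and 105 faster by limma and 1100 higher and 1071 lower by edgeR, and in batches 2 and 6 the counts were those without it.

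Over all batches decay calls were 1 slower (fbp) in the joint fit and with batches 2 and 6 only, and 1518 slower and 75 faster with batches 3 and 4 only. Within batches 3 and 4, slower and faster calls were 574 and 526 over 0 to 16 min, 652 and 121 with equal library sums, 742 and 566 centred, 947 and 143 scaled by ssrA and rnpB, and 977 and 135 with no filter. Faster calls alone moved to 122 with recomputed spike-in factors, 11 over 0 to 4 min and for 4 over 0 min (equal slopes by construction), 24 and 254 with pseudocounts of 0.1 and 5, and 25 with the filter at 50, where fewer genes were tested. Without 1 culture they were 827 to 1390 slower and 44 to 73 faster. Without the 2 min libraries they were 1458 and 70. Within batches 2 and 6 slower calls fell to 0 over 0 to 4 min, for 4 over 0 min, with no filter and with equal library sums by limma, and without 1 culture were 1 to 163 slower and 0 to 108 faster, the highest without the culture labelled fbp of batch 2. Leaving out 1 of 2 leaves a lone culture, assumed to vary like the others. With the filter at 50, 1784 and 1764 genes decayed under the labels parent and fbp, of fewer tested.

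At 0 min over all batches DESeq2 called 59 higher and 24 lower, leaving out 1 culture 0 to 6 and 0 to 10 by edgeR (6 and 10 without the culture labelled fbp of batch 6), batches 2 and 6 only 1 and 1, and batches 3 and 4 only 1049 and 1047. Within batches 3 and 4 the filter at 50 left 687 and 694, of fewer genes, and leaving out 1 culture 931 to 1014 and 948 to 1014. Within batches 2 and 6 higher calls were 0 with equal library sums by edgeR and 2 by DESeq2, and without 1 culture 0 to 4 higher and 1 to 92 lower. With the preset correlation camera called 6 lists for decay over all batches, 18 in batches 2 and 6 and 5 in batches 3 and 4, and for levels 6, 10 and 10.

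Named genes that reversed in decay within batches 3 and 4 were tdcA (-0.196 over 0 to 4 min and for 4 over 0 min, -0.00182 with pseudocount 0.1), cysU (-0.0283 with pseudocount 0.1), fliF (-0.00772) and fliL (-0.281) over 0 to 4 min and for 4 over 0 min, fliL also (-0.0847) with pseudocount 0.1, and flgK (0.0159) and adhE (0.0843) over 0 to 16 min. The level of rnb reversed with batches 2 and 6 only (-0.18), where it lay at the floor. Depth limits genes near the floor of 1: 14 of the 75 faster genes had under 10 CPM under the label parent.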

Other observations

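The test of sulfate and cysteine genes was chosen only after the result was seen; the tests of short-lived RNAs and of genes near fbp were written down before their own values were seen, though after the patterns they address.

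Most of the sulfate and cysteine genes tested were higher in the libraries labelled fbp of batches 3 and 4, libraries that went against their labels. The list was drawn up on these samples, so it is not independent evidence of a direction, and its enrichment was not tested. Beyond the 8 among the 10 largest rises, 11 further genes of a list of 28 sulfate and cysteine genes were tested, cysK (3.12) and cysM (3.91) among them. Of these 9 were higher and 2 lower by edgeR, 81.8% higher against 35.4% of all genes, with a median log2 difference of 3.12. In batches 2 and 6 their median was -0.00347. Since low pnp and the label were confounded in batches 3 and 4, the source of these rises is open.

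In batches 2 and 6, tabA (3.30) and, by DESeq2, its neighbour yjgL (2.31) were higher in the libraries labelled fbp, and tabA starts 19.3 kb from the end of fbp. Whether genes near the deletion differ more than others was tested on 62 genes within 50 kb of fbp. Their median size of difference was 0.23 on the log2 scale, against 0.23 for 2777 windows elsewhere, at percentile 55.9, so a general effect on the neighbourhood was argued against. What raised tabA was not tested.

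Whether short-lived RNAs slowed most in the libraries labelled fbp of batches 3 and 4 was tested with rates from other libraries. Across genes, which are not independent replicates, the rate in the libraries labelled parent of batches 2 and 6 and the label difference in batches 3 and 4 had a Spearman's rho of -0.226. In batches 2 and 6 the rate in the culture labelled parent of batch 2 and the label difference of batch 6, which share no library, gave -0.376, and the rate of batch 6 with the difference of batch 2 gave -0.0337. This check was added after the result was seen. Within batches 2 and 6 together it was -0.313, a value negative in part by construction because the difference subtracts that rate. One of the 2 separate pairs thus showed a stronger relation than batches 3 and 4 and the other next to none, so it cannot be held to be particular to batches 3 and 4, and whether it comes from pnp was not tested. Label differences in the 2 batch sets had an r of -0.11 across genes for decay and -0.04 for levels. Of the 1518 slower genes 33.3% also had a negative difference in batches 2 and 6, against 37.8% of all genes.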
